A study of Arabidopsis thaliana with 3 samples.

How the data were processed

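Total RNA of immature inflorescences was separated on a polyacrylamide gel, and RNA of 18 to 36 nt was cut out and made into libraries with an Illumina small RNA kit and sequenced on a HiSeq 2000, per the labels' protocols. The starting amount was 12 to 18 µg of total RNA. Each of the 3 deposited files gave, for each distinct sequence of 1 library, the number of reads, a chromosome, a position and a strand. These values are raw counts as deposited by the authors, with no normalization. The aligner, the adapter trimming and the genome build are not given in the sources used here.

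The content of the files was tested against the reference assembly TAIR10.1 with its RefSeq annotation. Of the 24-nt sequences of wt, 1415205 of 1415205 matched the nuclear or chloroplast reference perfectly at the given position and nowhere else, and the same held for the 197779 sequences of 21 nt and for each other length from 16 to 31 nt. In drb2 and drb4 the only exceptions at these lengths were sequences with an N. Over all lengths such sequences held 0.514% and 0.622% of reads and 0% in wt. Coordinates are therefore 1-based positions of TAIR10.1. Why wt held no sequence with an N is not given in the sources used here. If wt was sequenced or filtered otherwise than the mutants, comparisons with wt cannot be separated from that difference. Positions on the mitochondrion did not match the reference, so these reads were used only as a total. Sequences of 16 to 31 nt with several perfect matches were thus absent from the files, which has a direct effect on what can be measured. Of 90 mature miRNA sequences listed, 27 match several positions, including most of miR156, miR165, miR166, miR168 and miR390, and could not be measured. Repeated transposable elements are likewise covered only where their sequence is unique. Sequences of 32 and 36 nt were not searched for further matches. Of the 36-nt reads 23.4% in wt, 34.2% in drb2 and 38.5% in drb4 matched perfectly at the given position, and whether they had been trimmed was not tested.

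Counts were scaled to the total of all deposited reads of a library (RPM). Ratios of counts between libraries carry an exact 95% interval from the conditional binomial (Clopper-Pearson). Intervals of list medians are not exact and come from 200 bootstrap draws, that is random redraws of the counts. The interval of a ratio between quotients of read classes is a normal approximation. A count of 0 was replaced by 3 reads in ratios, so list medians hold such members at their bound. With 1 library per genotype the comparisons were drb2 with wt, drb4 with wt and drb4 with drb2, without a test across samples. The depth allowed narrow intervals for abundant loci, while for miRNAs with a few reads the interval spans several log2 units.

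The 5 nuclear chromosomes were divided into windows of 500 bp, kept with 100 or more 24-nt reads over the libraries. A window was called higher or lower where scaled counts differed 2-fold or more and the interval excluded 1. Windows were grouped by annotation and by whether they lay within 3 Mb of a centromere, with centres set at 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5. miRNA values are reads with exactly the mature sequence, for miRNAs with 30 or more reads, in a conserved and a young list. Reads on TAS loci and on listed protein-coding loci with secondary siRNAs were summed over both strands, at the same floor. Inverted repeats were found by aligning the reference with itself, with blastn 2.17.0 and a word size of 11. Arms had to be 150 bp or longer at 80% identity or more and within 3 kb of each other, which gave 661 repeats. For each list the median log2 ratio was given with its percentile among 10000 random lists of the same size, each member drawn from the 10 features nearest in abundance on either side. These pools include the members of the list itself, which make up most of the pools for the miRNA and TAS lists, so for those no percentile is reported. Overlap of the comparisons with the shared wt library was set beside 100 simulations of unchanged libraries.

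Loci and miRNAs named in the report followed a rule fixed before the data were examined. It took, for each mutant, the 6 highest and 6 lowest miRNAs with 100 or more reads in wt and the mutant together whose interval excluded 1. It further took the DCL4-dependent miRNAs, the TAS triggers and TAS loci, the 5 secondary siRNA loci with the most 21-nt reads, and the 4 inverted repeats with the most reads. For 24-nt windows it took the 4 highest and 4 lowest per mutant with 500 or more reads, at most 1 per 10 kb, and it added DRB2, DRB4 and the 3 most abundant miRNAs. Exceptions are stated where they occur.

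The window calls were tested on simulated counts at the depths of these libraries, with 20178 windows of which 200 were changed. In the comparison of drb2 with wt, 94 of 100 windows changed 2.5-fold and 100 of 100 changed 4-fold were recovered. For drb4 with wt, 93 and 99 of 100 were recovered. Among 19978 unchanged windows 10 and 28 were called, respectively. The simulated counts varied by counting error alone. These numbers therefore do not measure calls that come from differences between plants or library preparations. Alternatives were other scalings, floors of 30, 100 or 400 reads, windows of 2000 bp, a 4-fold rule, distinct sequences in place of reads, reads of 21 to 24 nt, and miRNA reads starting within 2 nt of the mature start. Scaling to reads of 21 to 24 nt and the ratio without miR159a reads were added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.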

Results

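Small RNAs were sequenced from immature inflorescences, flower stages 1 to 12, of Arabidopsis thaliana ecotype Col0. The 3 genotypes were the wild type (wt), the drb2-1 mutant and the drb4-1 mutant, with 1 library each. DRB2 and DRB4 are double-stranded RNA-binding proteins, and DRB4 is known as a partner of the Dicer-like enzyme DCL4. Each comparison asked how small RNA classes made by different Dicer-like enzymes changed without DRB2 or DRB4, and whether both mutations moved them in opposite directions. The deposited counts summed to 14601427 reads in wt, 16126564 in drb2 and 10346406 in drb4, over 2795214, 3483278 and 2297681 distinct sequences. With 1 library per genotype no difference has a replicate check, no p-value was computed, and every comparison is between libraries. Intervals are 95% intervals that cover counting error only, and PCR copies of a molecule are not separable from independent molecules. Below, a single locus or miRNA is called higher or lower where this interval of its ratio excluded 1.

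The mutated genes themselves carried few small RNAs. DRB2 (AT2G28380, chromosome 2, 12133732 to 12136241) had 8 reads of 21 nt in wt, 9 in drb2 and 7 in drb4. At DRB4 (AT3G62800, chromosome 3, 23225526 to 23227512) 0, 0 and 1 such reads were counted, and a count of 0 allows up to 3 reads. Reads of 24 nt at DRB2 numbered 3, 10 and 18. Small RNA reads do not measure the mRNA, so these values check the genotype labels only weakly.

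Fragments of longer RNAs differed strongly between the libraries. Reads on tRNA, rRNA, snRNA and snoRNA genes made up 8.53% of the wt library, 1.03% of drb2 and 3.76% of drb4. Chloroplast reads made up 2.23%, 0.889% and 3.47%, and mitochondrial reads 1.64%, 0.592% and 1.85%. A 36-nt sequence of the snoRNA gene AT2G08765 (chromosome 2, 15029623 to 15029658), named after its values were seen, alone had 370873 reads in wt, 3967 in drb2 and 16556 in drb4. These reads enter the total to which all values below were scaled, so the scaling was varied. Relative to scaling by all reads, leaving out these fragments shifted every log2 ratio to wt by -0.15 in drb2 and -0.05 in drb4. The median of ratios over genomic windows shifted it by -0.28 and -0.07, the reads of 21 to 24 nt by -0.17 and -0.05, and the conserved miRNA reads by 1.05 and -0.54. Between drb4 and drb2 the 4 shifts were 0.10, 0.21, 0.12 and -1.59, in the same order. RPM stands for reads scaled to the total of a library. All ratios below are relative to scaling by all reads unless another scaling is named.

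Reads of 24 nt, the size of Pol IV-dependent siRNAs cut by DCL3, were the main class in each library. They made up 59.5% of wt reads, 68.1% of drb2 reads and 65.4% of drb4 reads. The 21-nt class, which holds most miRNAs and DCL4 products, fell from 8.17% in wt to 5.69% in drb2 and stood at 9.09% in drb4. The 22-nt class was 0.499 times its wt level in drb4 (interval 0.497 to 0.501), with 3.58% against 7.18% of reads, and 1.02 times in drb2. Medians over the genome differed from these totals in 1880 windows with 100 or more 21-nt reads, named here after their values were seen. Their median log2 ratio was 0.14 in drb2 and -0.59 in drb4. In drb2 6.12% of these windows were at least 2-fold higher and 9.20% lower, and in drb4 5.37% and 28.4%. The drb2 median was negative without structural and organellar reads (-0.012), by the median of ratios (-0.14) and by reads of 21 to 24 nt (-0.024). Reads of 23 nt rose 1.43-fold in drb2, to 13.1%. As a result, there were 7.28 reads of 24 nt for each 21-nt read in wt, 12.0 in drb2 and 7.20 in drb4. The log2 ratio of these quotients was 0.72 for drb2 against wt (interval 0.71 to 0.72), -0.02 for drb4 against wt (-0.02 to -0.01) and -0.73 for drb4 against drb2. Counting each distinct sequence once changed the direction of the last comparisons, with log2 ratios of 0.14, 0.57 and 0.43. Without reads of miR159a, an alternative chosen after the data were seen, the ratios were 0.51, 0.25 and -0.25.

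**Figure D1:**
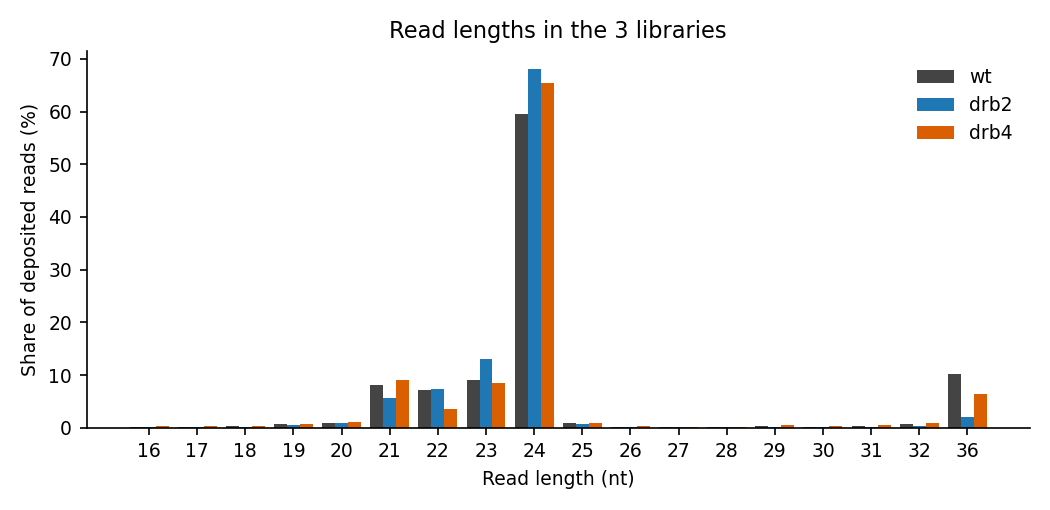
Share of deposited reads (vertical axis, %) by read length (horizontal axis, nt; only lengths present are drawn) in the wt, drb2 and drb4 libraries, 1 bar per library. Reads of 24 nt form the tallest bars at 59.5%, 68.1% and 65.4%, and the 22-nt bar of drb4 stands at 3.58% against 7.18% in wt.

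Over the genome, drb2 had more 24-nt windows above wt than below it, mainly near the centromeres. Of 20178 windows of 500 bp with 100 or more 24-nt reads over the libraries, 1657 (8.21%) were at least 2-fold higher in drb2 than in wt and 426 (2.11%) were at least 2-fold lower. Within 3 Mb of the centromeres 1208 of 11909 windows were higher and 121 lower, and on the arms 449 of 8269 were higher and 305 lower. Among 5797 windows on annotated pseudogenes and transposable element genes, 430 were higher and 29 lower, against 325 and 139 of 3496 windows on protein-coding genes and 8.37% and 2.08% of 10106 intergenic windows. The annotation has no separate list of transposable elements, so others count as intergenic. The median log2 ratio was 0.32 near the centromeres and 0.15 on the arms, and the arm median turned negative under each scaling except those by all reads and by conserved miRNAs. The split of higher to lower windows depended on the scaling, with 1067 to 558 without structural and organellar reads, 1028 to 569 by reads of 21 to 24 nt, 742 to 709 by the median of ratios and 74.6% to 0.803% of windows by conserved miRNA reads.

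Individual windows changed in drb2 between near absence and abundance. A mostly intergenic window that overlaps the start of ASY2, a gene related to the meiotic axis gene ASY1 (chromosome 4, 15548501 to 15549000), held 2 reads of 24 nt in wt and 1076 in drb2, a log2 ratio of 8.93 (7.07 to 11.98). The drb4 library had 479 reads there. A window 308 bp from the lncRNA gene AT2G09760 (chromosome 2, 19263501 to 19264000) held 9 reads in wt, 2782 in drb2 and 12 in drb4. Windows 593 bp from the peptide hormone gene RALF23 (chromosome 3, 5643501 to 5644000) and near AT2G34730 (chromosome 2, 14653501 to 14654000) rose from 2 reads each to 503 and 471. The lowest ratio lay over exons and introns of AT1G14780 (chromosome 1, 5091501 to 5092000), with 2055 reads in wt, 2 in drb2 and 24 in drb4, a log2 ratio of -10.15 (-13.19 to -8.29). Next came a window 1418 bp from AT1G05790 (chromosome 1, 1739001 to 1739500), with 58.7 RPM in wt and 0.062 in drb2. A mostly intergenic window that overlaps the end of the lncRNA gene AT3G07775 (chromosome 3, 17520001 to 17520500) fell from 1985 reads to 3, and a window partly over an untranslated exon part of AT3G57480 (chromosome 3, 21277001 to 21277500) from 609 to 1.

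In drb4, higher and lower 24-nt windows were about equally frequent at the main settings, at 4.18% and 4.03% of windows, but other settings tipped this balance either way. There were 132 higher and 305 lower under a 4-fold rule, 224 and 351 at a floor of 400 reads, and 6.38% and 3.74% of windows at a floor of 30 reads. Near the centromeres 582 were higher and 248 lower, while on the arms 262 were higher and 566 lower. Scaling by conserved miRNA reads changed the split to 201 higher and 2281 lower. The highest ratios lay at the same ASY2 and AT2G34730 windows, with log2 ratios of 8.40 and 8.01. Near FBS3 (183 bp away, chromosome 4, 2566501 to 2567000) 24-nt reads numbered 6 in wt, 1019 in drb2 and 1057 in drb4. Over exons and introns of HAK5, a high-affinity potassium transporter gene (chromosome 4, 7799501 to 7800000), they stood at 2.19, 2.54 and 297 RPM, so that this rise of 7.08 on the log2 scale was not seen in drb2. The lowest ratio was 257 bp from PSAL, a photosystem I subunit gene (chromosome 4, 7520501 to 7521000), with 491 reads in wt, 12 in drb2 and 1 in drb4. A window 30 bp from the lncRNA gene AT5G07295 (chromosome 5, 19830001 to 19830500) held 1469, 0 and 3 reads. Windows 482 bp from AT3G62528 (chromosome 3, 23130501 to 23131000) and partly over the noncoding gene AT4G02895 (chromosome 4, 7382501 to 7383000) fell in drb4 from 947 to 2 and from 374 to 1, with 904 and 343 reads in drb2. Between the mutants, 556 windows were higher and 1430 lower in drb4 than in drb2. This became 949 to 982 by the median of ratios, 743 to 1137 by reads of 21 to 24 nt and 143 to 18478 by conserved miRNA reads.

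With scaling by all reads, windows that changed 2-fold in both mutants mostly did so in the same direction. Across 20174 windows the log2 ratios of both mutants to wt correlated with r = 0.43, where simulated unchanged libraries against the same wt library gave 0.47. Their covariance was 0.263 against a simulated 0.0235. Of the windows higher in drb2, 49 were lower in drb4, where independent lists would share 66.8. The number both higher was 312 (69.3 for independent lists), the number both lower 178 (17.2), and 31 were lower in drb2 and higher in drb4 (17.8). Under scaling by conserved miRNA reads the median 24-nt window stood on opposite sides of wt, at a log2 ratio of 1.29 in drb2 and -0.37 in drb4. The number higher in drb2 and lower in drb4 was then 1035, against 1701 for independent lists. Both ratios use the only wt library, so part of the excess of shared changes may come from it, and windows are not independent replicates.

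Most of the miRNAs that could be measured fell in drb2. Of 38 conserved sequences listed, only 14 match 1 genomic position and could be measured. Of these 14, 11 passed the floor of 30 reads and 11 were lower in drb2 than in wt, with a median log2 ratio of -1.34 (-1.42 to -1.21). miR159a, the most abundant of the miRNAs that could be measured and a regulator of MYB genes, had 413474 reads in wt and 222924 in drb2, a log2 ratio of -1.03. miR159b and miR396b, the next in abundance, were at -0.91 and -1.34, and both miR159 members turned slightly positive when scaled to conserved miRNA reads. Among miRNAs with 100 or more reads, the 6 lowest ratios were those of miR839 (-2.41), miR408 (-2.19), miR167d (-1.87), miR822 (-1.85), miR472 (-1.77) and miR403 (-1.75), and each of these stayed lower under every scaling. Of the 32 young miRNAs past the floor 24 were lower and 1 was higher, with a median of -1.17. The exception was miR173 (chromosome 3, 8236161 to 8236182), which triggers siRNA production from TAS1 and TAS2 transcripts and had 11868 reads in wt and 16446 in drb2, a log2 ratio of 0.33 (0.29 to 0.36). Scaled to conserved miRNA reads the conserved and young medians were -0.29 and -0.12. This scaling holds the sum of the conserved miRNAs at its wt level, and miR159a made up 83.5% of that sum in wt. It therefore cannot test whether the conserved miRNAs fell as a class.

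In drb4 the same miRNAs mostly stood slightly above wt, but DCL4-dependent ones fell. Of the conserved miRNAs 9 were higher and 0 lower, with a median log2 ratio of 0.42 (0.38 to 0.45), which became -0.12 when scaled to conserved miRNA reads. That scaling fixes their sum, so it does not test their rise as a class. Among the young miRNAs 16 were higher and 4 lower, with a median of 0.52, or -0.02 under that scaling. miR159a, miR159b and miR396b had log2 ratios of 0.55, 0.56 and 0.42, the last of which turned negative under that scaling. miR839 (chromosome 1, 25279138 to 25279158), a young miRNA cut by DCL4, dropped 21.9-fold from 5510 reads in wt to 178 in drb4, a log2 ratio of -4.46 (-4.68 to -4.24). Another DCL4-dependent miRNA, miR822 (chromosome 5, 897287 to 897307), dropped 10.8-fold from 11.4 RPM to 1.06. The DCL4-dependent miR869 had 1 read in wt, 0 in drb2 and 1 in drb4, too few for a comparison. The other lower young miRNAs were miR858 at -0.47 and miR840 at -2.14, the latter with 62 reads in wt and 10 in drb4 and named after its values were seen. Among miRNAs with 100 or more reads, the highest 6 ratios were those of miR860 (3.13, from 28 to 174 reads), miR391 (2.08), miR173 (1.54), miR867 (1.31), miR780 (1.14) and miR408 (1.12), which kept their direction under every scaling. miR828, the TAS4 trigger, had 1, 2 and 4 reads, and miR390, the TAS3 trigger, has several genomic copies and could not be measured. Between drb4 and drb2 the conserved median was 1.67 and the young median 1.54, and scaled to conserved miRNA reads they were 0.07 and -0.05.

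**Figure D2:**
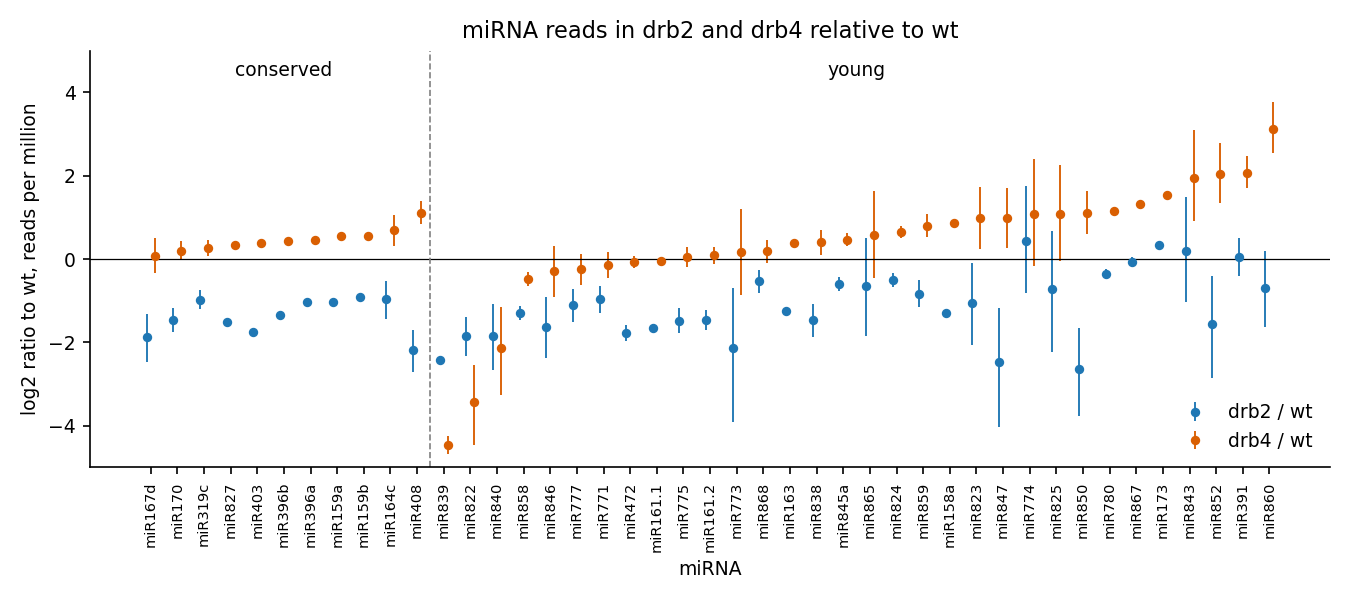
Log2 ratio of scaled reads (RPM) to wt (vertical axis) for each miRNA with 30 or more reads over the libraries (horizontal axis), in drb2 (blue) and drb4 (orange); bars are 95% counting intervals. The conserved miRNAs lie below 0 in drb2 and at or above 0 in drb4 with this scaling, though the drb4 median becomes -0.12 when scaled to conserved miRNA reads; miR839 and miR822 reach -4.46 and -3.43 in drb4.

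TAS loci, whose transcripts are cut by a miRNA and then processed into 21-nt trans-acting siRNAs, changed in amount in drb2 and in size in drb4. In drb2 the 21-nt reads were lower at 7 of the 7 loci past the floor, with a median log2 ratio of -1.10 (-1.12 to -1.04). TAS1b, TAS1c, TAS2 and TAS3b fell by 1.11, 1.12, 1.12 and 1.10 on the log2 scale, TAS3a by 0.89, TAS3c by 0.76 and TAS1a by 0.63. Under scaling to conserved miRNA reads the median was -0.06, and TAS1a, TAS3a and TAS3c turned positive. In drb4 the 21-nt median was -0.03. TAS2 (chromosome 2, 16539384 to 16540417) was lower at -0.58 and TAS1a at -0.24, while TAS1c (chromosome 2, 16537288 to 16538277) was higher at 0.37 but negative when scaled to conserved miRNA reads. TAS4 had 0 reads of 21 nt in wt and drb2 and 3 in drb4.

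Longer TAS reads rose in drb4. Reads of 22 nt were higher at 7 of 7 loci, with a median log2 ratio of 1.79 and a range from 0.39 at TAS2 to 2.33 at TAS1b, although TAS2 turned negative when scaled to conserved miRNA reads. At TAS1b (chromosome 1, 18549204 to 18550042) they increased from 98.8 to 495 RPM. Reads of 24 nt were also higher at 7 of 7 loci under every scaling, with a median of 1.32. TAS3c (chromosome 5, 23394005 to 23394500) rose most, from 11 reads of 24 nt in wt and 9 in drb2 to 313 in drb4, a log2 ratio of 5.33 (4.47 to 6.34). Over these loci together the 21-nt share of 21 to 24-nt reads was 66.8% in wt, 66.9% in drb2 and 46.3% in drb4. The 22-nt share was 27%, 25.4% and 42.2%, and the 24-nt share 4.64%, 5.81% and 8.47%, values that need no scaling between libraries. Summed over 21 to 24 nt, the median TAS ratio in drb4 was 0.48, and counted as distinct 21-nt sequences 0.42, both opposite in sign to the median for 21-nt reads. In drb2 the 22-nt and 24-nt reads fell with the 21-nt reads, with medians of -0.83 and -0.69, which became 0.21 and 0.36 when scaled to conserved miRNA reads. Between drb4 and drb2 the 21-nt median was 0.85, and -0.74 when scaled to conserved miRNA reads.

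**Figure D3:**
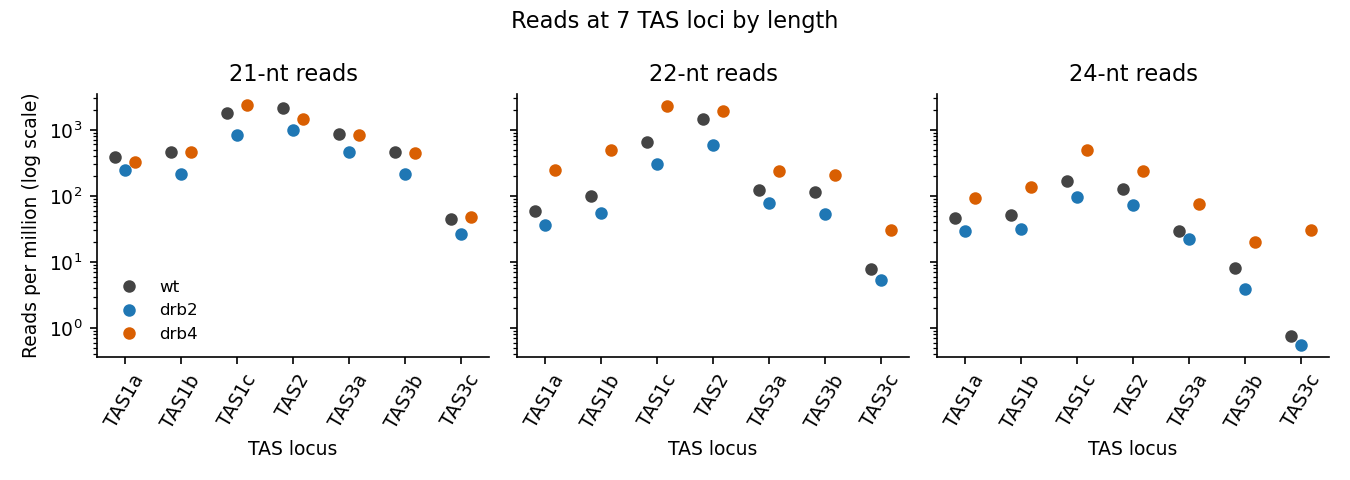
Scaled reads (RPM, vertical axis, log scale) of 21, 22 and 24 nt at 7 TAS loci (horizontal axis) in wt, drb2 and drb4, 1 point per library. The drb4 points lie above wt at each locus for 22 nt (TAS2 reverses when scaled to conserved miRNA reads) and for 24 nt, while for 21 nt 4 of the 7 loci were not distinguished from wt with this scaling, TAS2 and TAS1a were lower, at log2 ratios of -0.58 and -0.24, and TAS1c was higher at 0.37 (negative when scaled to conserved miRNA reads).

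At protein-coding loci with secondary siRNAs the median change of 21-nt reads was negative in both mutants, though in drb2 not when scaled to conserved miRNA reads. In drb2 17 of 21 loci were lower and 0 higher, with a median log2 ratio of -1.04 (-1.21 to -0.91), and this median lay at percentile 0.75 among matched random gene lists, which had a median of -0.17. It was 0.01 when scaled to conserved miRNA reads. In drb4 11 loci were lower and 3 higher, with a median of -0.90 (-1.09 to -0.42), at percentile 3.73. Random lists also fell in drb4, with a median of -0.53 and a 95% range of -0.96 to -0.066 that includes this value. Summed over the 21 loci the 21-nt reads rose from 524 RPM in wt to 668 in drb4, a direction that turned negative when scaled to conserved miRNA reads. AT1G12290 alone rose from 277 to 519 RPM, more than the sum did, so the other loci together fell. The 3 higher loci were AT1G12290 and, named after their values were seen, the disease resistance gene AT5G43740 (0.88) and the auxin response factor gene ARF4 (AT5G60450, 0.68). The pentatricopeptide repeat (PPR) genes AT1G63080, AT1G63130 and AT1G63150, on chromosome 1 between 23387574 and 23421714, fell by 1.38, 1.03 and 1.12 on the log2 scale in drb4 and by 0.99, 0.90 and 1.24 in drb2, where AT1G63080 and AT1G63130 turned positive when scaled to conserved miRNA reads. AT1G63230, chosen after its values were seen, had 56 reads in wt, 34 in drb2 and 4 in drb4. The auxin receptor gene AFB3 (AT1G12820) was at -1.11 in drb2 and -0.15 in drb4. The disease resistance gene AT1G12290 (chromosome 1, 4177917 to 4182593) had a log2 ratio of -1.31 in drb2 and 0.90 in drb4, but the miR472 gene lies within its annotated span, so its reads may include that precursor. Longer reads at these loci had positive medians in drb4, 0.80 for 22 nt and 0.62 for 24 nt, or 0.26 and 0.077 when scaled to conserved miRNA reads, but no random lists were made for these lengths. Of the 21 loci 10 were higher and 3 lower in 22-nt reads, and only 4 were higher and 0 lower in 24-nt reads. The 3 lower ones, named after their values were seen, were AT1G63080, AT1G63230 and AT5G16640. With reads of 21 to 24 nt together the drb4 median became 0.09. Between drb4 and drb2 the 21-nt median was 0.11 (-0.02 to 0.64), and -1.48 when scaled to conserved miRNA reads.

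Long inverted repeats, whose transcripts can fold into hairpins, gained 24-nt reads in drb4. The repeat on chromosome 3 from 1964170 to 1970000 has arms of 2799 bp at 99.0% identity. It lies over genes that include the noncoding AT3G01835 and AT3G01845 and part of the protein-coding AT3G06435. Its 24-nt reads rose from 289 RPM in wt to 3623 in drb4, a log2 ratio of 3.65 (3.6 to 3.69). Reads of its arms could be counted only where the arms differ, since sequences with several perfect matches are absent. Among the reads counted in wt the most frequent size was 22 nt, at 1326 RPM, and this size had a log2 ratio of -0.20 in drb4. At the repeat formed by AT3G44570 and AT3G44580 (chromosome 3, 16158283 to 16161628) 24-nt reads rose from 772 to 4106 RPM, a log2 ratio of 2.41 (2.38 to 2.44). The repeat on chromosome 1 from 24721047 to 24721524 had a log2 ratio of 0.62, and that on chromosome 3 from 17728565 to 17728966 a ratio of 0.30, which turned negative when scaled to conserved miRNA reads. Reads of 21 nt at these 4 repeats had log2 ratios of 1.02, 1.08, 0.90 and 1.19 in drb4. In drb2 their 24-nt reads were lower, at -0.60, -0.84, -0.79 and -0.30, and each of these became positive when scaled to conserved miRNA reads.

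**Figure D4:**
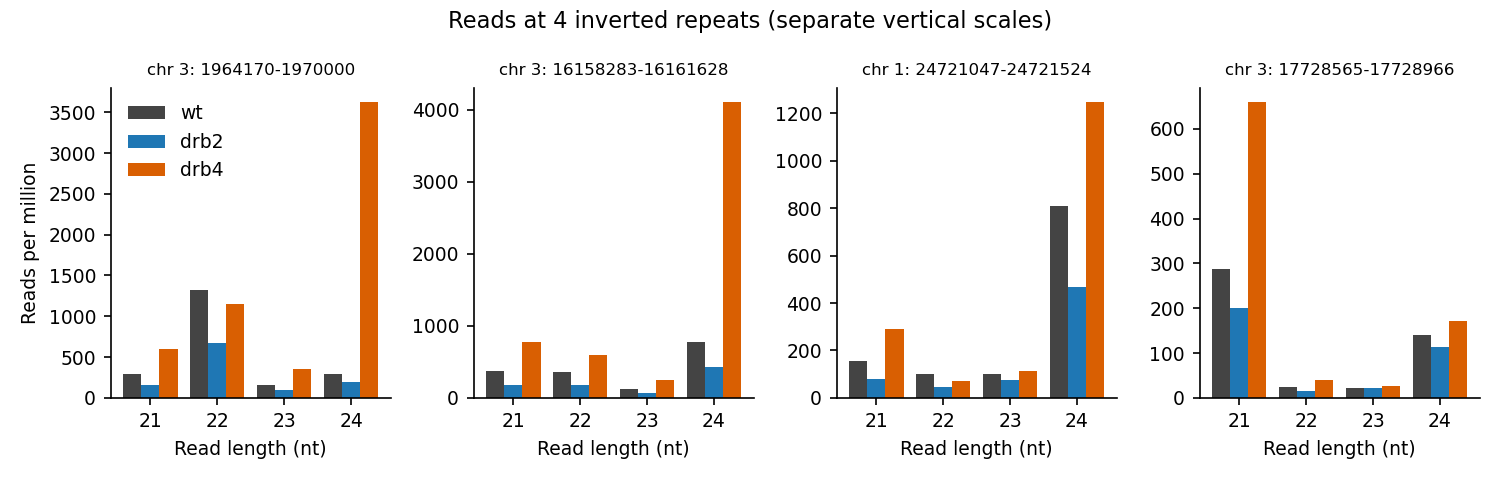
Scaled reads (RPM, vertical axis, a separate scale in each panel) by read length in nt (horizontal axis) at the 4 inverted repeats with the most reads, in wt, drb2 and drb4. The drb4 bars for 24 nt reach 3623 and 4106 in the left panels, against 289 and 772 in wt; the direction of the 24-nt change in the right panel, and of the drb2 changes in 24-nt reads, reverses when scaled to conserved miRNA reads.

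The same held, less strongly, for the wider set of inverted-repeat windows, which includes windows of the repeats above. Neighbouring windows of a repeat are not independent, while random lists drew windows singly. The percentiles below thus count windows, not repeats, and are not a separate check on the repeats above. In drb4 67 of 496 windows past the floor were at least 2-fold higher in 24-nt reads and 9 at least 2-fold lower. The 24-nt median was 0.31, above each of 10000 random lists (percentile 100), which themselves had a median of 0.19. This 24-nt median became -0.24 when scaled to conserved miRNA reads, a scaling that shifts the random lists by the same amount. The 21-nt median, over 108 windows past the floor, was 0.12 where random lists had -0.52. It became -0.43 with the miRNA scaling, which shifts random lists alike. The 22-nt median, over 139 windows, was -0.50 where random lists had -1.44. In drb2 the medians were -0.31 for 21 nt, 0.08 for 22 nt and 0.15 for 24 nt. The last was at percentile 0.15, where random lists had 0.22. The 24-nt median in drb2 was negative under 3 of the scalings (-0.0023 without structural and organellar reads, -0.13 by the median of ratios and -0.01 by reads of 21 to 24 nt), and the 21-nt median was 0.73 when scaled to conserved miRNA reads. The 22-nt median in drb2 turned negative under the same 3 scalings. Between drb4 and drb2 the medians were 0.18, -0.71 and 0.11 for 21, 22 and 24 nt, and -1.41, -2.30 and -1.48 when scaled to conserved miRNA reads.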

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

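All of the tests given here were chosen only after the data were seen. They concern reads outside the measured classes that stood above their level in the wt library in drb4, and each library was measured once. Reads of 16 to 20 nt were 1.18 times as frequent in drb4 as in wt, with 2.44% of wt reads, 1.99% of drb2 reads and 2.87% of drb4 reads. Reads of 25 to 28 nt were 1.17 times as frequent, with 1.55%, 1.11% and 1.82%. Reads of 29 to 32 nt were 1.30 times as frequent, with 1.80%, 0.682% and 2.35%. Chloroplast reads were 1.55 times and mitochondrial reads 1.12 times as frequent in drb4 as in wt. In drb2 each of these 5 classes was less frequent than in wt. The 36-nt class, the most abundant outside the measured sizes, was lower instead, at 0.617 times wt in drb4 and 0.196 times in drb2. A 29-nt fragment of the chloroplast tRNA gene trnD had 33354 reads in wt, 15981 in drb2 and 45393 in drb4. No explanation was tested for these classes.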

How the results depend on the processing

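The tests chosen only after the data were seen were scaling to reads of 21 to 24 nt and the ratio without miR159a reads. No paired analysis was possible because each genotype had 1 library. Of 230 alternative values, 103 kept their direction and stayed within their interval or within 1.5 times the count, 111 moved beyond that and 16 reversed. A change of sign counted as reversed only where the main interval excluded 0, and 9 of the 111 moved values also changed sign. Windows are given as a percentage of those tested, and whether they moved was judged on their number. Values below are given in the order drb2 against wt, drb4 against wt and drb4 against drb2. A scaling adds the same shift to every log2 ratio, so its effect follows from its construction, and so does the effect of a floor, window size or fold rule on a number of windows. For the other changes the cause was not tested. Restricting to reads with 1 genomic position gave no separate value, since for lengths of 16 to 31 nt on the nuclear and chloroplast genomes the files hold only such reads. Scaling left the correlation between the mutants as it was.

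The log2 ratio of 24-nt to 21-nt reads was 0.71, -0.0085 and -0.72 without structural and organellar reads. It was 0.14, 0.57 and 0.43 for distinct sequences and 0.51, 0.25 and -0.25 without miR159a reads, so that drb4 against wt reversed in both and drb4 against drb2 for distinct sequences.

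With scaling without structural and organellar reads, 5.29%, 3.51% and 3.54% of windows were higher and 2.77%, 4.42% and 5.82% lower in 24-nt reads, and 47 windows were higher in drb2 and lower in drb4. Medians were -1.50, 0.37 and 1.77 for conserved miRNAs and -1.33, 0.47 and 1.64 for young miRNAs. TAS loci had -1.26, -0.086 and 0.95, and secondary siRNA loci -1.19, -0.95 and 0.21. Inverted-repeat windows had -0.47, 0.063 and 0.28 for 21 nt, -0.075, -0.56 and -0.61 for 22 nt and -0.0023, 0.25 and 0.21 for 24 nt.

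With scaling to conserved miRNA reads, 74.6%, 0.996% and 0.709% of windows were higher and 0.803%, 11.3% and 91.6% lower in 24-nt reads, and 1035 windows were higher in drb2 and lower in drb4. Medians were -0.29, -0.12 and 0.075 for conserved miRNAs and -0.12, -0.021 and -0.054 for young miRNAs. TAS loci had -0.056, -0.58 and -0.74, and secondary siRNA loci 0.012, -1.44 and -1.48. Inverted-repeat windows had 0.73, -0.43 and -1.41 for 21 nt, 1.13, -1.05 and -2.30 for 22 nt and 1.2, -0.24 and -1.48 for 24 nt. Reversed under this scaling were the drb4 medians against wt of both miRNA lists and of 24-nt reads at inverted repeats, and the drb2 medians of secondary siRNA loci and of 21-nt reads at inverted repeats. For the conserved miRNAs this is no independent check, since the scaling divides by their own sum. Between the mutants, young miRNAs, TAS loci and 24-nt reads at inverted repeats reversed. With a main interval that included 0, the sign also changed for secondary siRNA loci between the mutants and for 21-nt reads at inverted repeats in drb4 against wt and against drb2.

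With scaling by the median of ratios, 3.68%, 3.34% and 4.7% of windows were higher and 3.51%, 4.54% and 4.87% lower in 24-nt reads, and 37 windows were higher in drb2 and lower in drb4. Medians were -1.62, 0.35 and 1.88 for conserved miRNAs and -1.45, 0.45 and 1.75 for young miRNAs. TAS loci had -1.39, -0.10 and 1.07, and secondary siRNA loci -1.32, -0.96 and 0.32. Inverted-repeat windows had -0.60, 0.047 and 0.39 for 21 nt, -0.20, -0.57 and -0.49 for 22 nt and -0.13, 0.24 and 0.33 for 24 nt.

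With scaling to reads of 21 to 24 nt, 5.09%, 3.61% and 3.68% of windows were higher and 2.82%, 4.38% and 5.63% lower in 24-nt reads, and 43 windows were higher in drb2 and lower in drb4. Medians were -1.51, 0.38 and 1.79 for conserved miRNAs and -1.34, 0.48 and 1.66 for young miRNAs. TAS loci had -1.27, -0.078 and 0.97, and secondary siRNA loci -1.20, -0.94 and 0.23. Inverted-repeat windows had -0.48, 0.071 and 0.30 for 21 nt, -0.087, -0.55 and -0.59 for 22 nt and -0.014, 0.26 and 0.23 for 24 nt.

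Counting distinct sequences gave 1.98%, 1.44% and 1.75% of windows as higher and 1.44%, 2.32% and 2.87% as lower. TAS loci then had -0.52, 0.42 and 0.97 and secondary siRNA loci -0.85, -0.47 and 0.39. Inverted-repeat windows had -0.32, 0.04 and 0.39 for 21 nt, -0.12, -0.37 and -0.25 for 22 nt and -0.047, 0.20 and 0.19 for 24 nt. The drb2 median for 24 nt reversed here, as it did under the scalings without structural and organellar reads, by the median of ratios and to reads of 21 to 24 nt. The drb2 median for 22 nt changed sign under the same 4 settings, and that of TAS loci in drb4 against wt changed sign here, each with a main interval that included 0.

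With a floor of 400 reads, 8.39%, 2.96% and 2.54% of windows were higher and 2.14%, 4.64% and 7.4% lower, the correlation was 0.381 and 26 windows were higher in drb2 and lower in drb4. The 24-nt median of inverted repeats in drb2 was 0.10.

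With a floor of 30 reads, 9.26%, 6.38% and 4.18% of windows were higher and 2.46%, 3.74% and 7.16% lower, the correlation was 0.423 and 65 windows were higher in drb2 and lower in drb4.

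With windows of 2000 bp, 4.96%, 2.64% and 2.12% of windows were higher and 1.75%, 3.06% and 4.83% lower, the correlation was 0.407 and 27 windows were higher in drb2 and lower in drb4.

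Under a 4-fold rule 0.922%, 0.654% and 0.927% of windows were higher and 0.828%, 1.51% and 1.87% lower. Without a floor beyond 1 read in each library the conserved miRNA median in drb2 was -1.03. Reads of 21 to 24 nt in place of 21-nt reads gave medians of -1.0, 0.48 and 1.33 at TAS loci and -1.10, 0.092 and 0.86 at secondary siRNA loci, the drb4 value against wt being reversed at the latter and changed in sign at the former, where the main interval included 0. Depth limits the miRNAs and loci with few reads, such as miR869, miR828 and TAS4, for which no change was detectable.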

Other observations

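The tests chosen only after the result was seen were both on miRNAs against 24-nt siRNAs, the change of 22-nt windows and the 24-nt reads of TAS loci, as were the loci named in the last paragraph.

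The conserved miRNAs that could be measured fell in drb2 while 24-nt windows rose slightly when both were scaled to all reads. The fall did not rest on miR159a, which held 83.5% of the wt reads of conserved miRNAs, because the others summed had a log2 ratio of -1.12. Relative to conserved miRNAs the median 24-nt window in drb2 was 1.29 higher on the log2 scale, which may come from fewer miRNAs, from more 24-nt siRNAs or from library preparation. These cannot be told apart with 1 library per genotype. Classes outside both give no steady reference, because they differed too. Structural RNA reads made up 8.53% of wt and 1.03% of drb2, and chloroplast reads 2.23% and 0.889%.

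Reads of 22 nt were less frequent in drb4. A size bias of the gel slice or of trimming would also lower 22-nt fragments of structural and organellar RNA, but relative to 21 and 23 nt these stood at 1.02 times wt, where all reads stood at 0.490. Loss at a few abundant loci was excluded too, since without the 100 windows richest in wt 22-nt reads, which held 33.5% of them, the ratio was 0.453. The median 22-nt window changed by -1.66 on the log2 scale in drb4 and by 0.18 in drb2 (-0.10 by the median of ratios), so a candidate explanation is a change in siRNA processing without DRB4. The loss was not general, because 22-nt reads rose in drb4 at 7 of 7 TAS loci, with a median of 1.79 (TAS2 turned negative when scaled to conserved miRNA reads), and at 10 of 21 secondary siRNA loci. A difference between plants or preparations of the single libraries cannot be told apart from it.

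Long inverted repeats gained 24-nt reads in drb4. Copies of a few sequences alone would leave the number of distinct sequences unchanged, but at the AT3G44570 repeat this rose from 995 to 1535, a scaled ratio of 1.88. Scaled reads there rose more, 5.32-fold, so each sequence also had more reads. The test therefore does not exclude that copies of some sequences make up much of the gain. TAS loci also gained 24-nt reads in drb4, with a median log2 ratio of 1.32, and not in drb2, at -0.69 (0.36 when scaled to conserved miRNA reads), so another Dicer-like activity might act on precursors that DRB4 otherwise serves. Reads of 21 nt did not fall as a set beside this gain. At the 4 repeats they had log2 ratios of 1.02, 1.08, 0.90 and 1.19 in drb4. At TAS loci their median was -0.03, with 2 loci lower and 1 higher, or -0.58 when scaled to conserved miRNA reads. The explanation by another Dicer-like activity stays open with 1 library per genotype.

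In drb2 61 of the 24-nt windows were at least 16-fold higher and 89 lower, and in drb4 52 and 86. The mutants had 24 of the higher and 36 of the lower windows in common. Both were compared with the same wt library, so a window unusual in wt counts in both. Chromosome arms held 73.8% and 82.0% of the higher and lower windows in drb2 and 65.4% and 76.7% in drb4, but 41.0% of the windows tested. Among 145 protein-coding genes with 300 or more 21-nt reads, 13 were at least 4-fold higher in drb4 and 16 lower, against 0 and 4 in drb2. Of these, 5 of the higher and 1 of the lower genes in drb4 overlapped an annotated miRNA gene, as did all 4 in drb2, so those reads may be of the miRNA. AT1G33420 had 25 reads in wt, 15 in drb2 and 1055 in drb4, and NDL2 (AT5G11790), which overlaps a miRNA gene, had 43, 20 and 1042. AT1G49260 had 358, 257 and 5 reads, and CXIP2 (AT2G38270) had 626, 832 and 32. The 24-nt reads of these genes moved the same way between wt and drb4. They went from 8 to 289 at AT1G33420, 14 to 33 at NDL2, 4700 to 451 at AT1G49260 and 8384 to 1919 at CXIP2. Over all 145 genes the median log2 ratio of 21-nt reads in drb4 was -0.68.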
